A study of Mus musculus with 15 samples.

How the data were processed

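RNA from snap-frozen tissue of 15 mouse samples was sequenced after poly(A) selection with a strand-marking (dUTP) library kit: 5 CIC LOF, 3 HrasG12V and 4 p53 KO tumours and 3 wild-type thymi, all of mixed C57BL/6-129 background. The unit of the deposited table is signal, meaning read counts per gene that the authors divided by 1 size factor per library. Every value above 0 was a whole multiple of its library's smallest step within 1e-06, so whole reads were recovered. Upstream steps per the submitters' processing notes were FastQC, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.19 and DESeq2 on GRCm38. The counting tool, annotation and strand setting were not given in the sources used here, so near-identical copies and overlapping genes are uncertain. The table held 23337 gene symbols, 2842 of them without a read. Positions came from the RefSeq annotation of GRCm38, which matched 20755 symbols directly and 2312 by an older symbol and left 270 unmatched. Libraries held 15973 (CIC LOF 4) to 19020 (thymus 3) genes above 0. Reads carry no molecular identifiers, so the floor of 3 counts used for a gene without reads covers counting error only. No 2 replicate libraries were copies of each other, with a chi-square per gene between replicate pairs of at least 9.58.

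Groups, the 7 comparisons, 23 gene lists, the test and its alternatives were fixed before the data were examined. Values were log2 transformed after adding 1, and the 15646 genes at 10 or more in at least 3 samples were tested with limma 3.58.1 (R 4.3.3, moderated with a mean trend) in 1 model of all 15 samples, with a 5-level factor for the Etv4 genotype split. A gene changed at a Benjamini-Hochberg adjusted p under 0.05; all tests were two-sided. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Of 161 list tests, 64 passed with the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.690; 10 at an unadjusted p under 0.05) and 8 with fry. Named genes follow a rule: Cic, Hras, Kras, Trp53 and Etv4; the 6 highest and 6 lowest log2 fold changes among changed genes whose groups do not overlap and whose higher mean is at least 100; and per list up to 4 passing members of lowest p, with any passing CIC target. Predicted genes, pseudogenes, receptor segments, sex-linked and mitochondrial genes were left out of the second part. Expected overlaps are the product of both counts over the genes tested, and unchanged groups were simulated 20 times, thymus included.

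Simulations changed 40 genes at each fold in the 7 designs. Limma recovered 0% at 1.5-fold, 2.5% to 17.5% at 2-fold, 40% to 47.5% at 4-fold and 67.5% to 90% at 16-fold. Of its calls 2.99% to 9.41% were false, but the wider spread of p53 KO was not simulated. Alternatives were pseudocounts of 0.5 and 10, no filter, a filter at 50, quantile and TMM scaling, the 2 compared groups alone, array weights, a robust prior, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a 2-fold minimum, each library left out, each Etv4 genotype alone, and lists without shared genes. Leaving out CIC LOF 1 with p53 KO 2, and p53 KO 1 with p53 KO 3, was chosen after seeing the data. Plots were drawn with matplotlib 3.10.9. No library was left out of the reported fits.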

Results

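RNA sequencing measured gene expression in 12 mouse T-cell lymphoblastic tumours and 3 normal thymi. T-cell acute lymphoblastic leukaemia (T-ALL) is a cancer of immature T cells, which mature in the thymus. In 5 tumours (CIC LOF) both copies of Cic, which encodes a repressor that RAS-ERK signalling switches off, were floxed and a tamoxifen-activated Cre recombinase was present in all tissues. In 3 tumours (HrasG12V) the same recombinase and diet switched on an oncogenic Hras placed at the Kras locus. The other 4 tumours (p53 KO) came from untreated mice labelled as knockout for Trp53, which encodes the p53 tumour suppressor, and the thymi came from untreated wild-type mice. Replicates 3, 4 and 5 of CIC LOF also carried a LacZ allele at 1 copy of Etv4. Every CIC LOF and HrasG12V mouse and no p53 KO or wild-type mouse received tamoxifen and Cre, so genotype and treatment were confounded. Depth was 20881583 (HrasG12V 3) to 33933352 (CIC LOF 1) reads per library.

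Levels are normalised read counts given as mean ± SD, with n = 5 CIC LOF, n = 3 HrasG12V, n = 4 p53 KO and n = 3 thymus libraries. Each adjusted p is limma's, Benjamini-Hochberg adjusted over the 15646 genes tested or, for gene lists, over 161 list tests (where so stated over the list alone, giving members higher, then lower). List scores are mean log2 differences from thymus. The labels name each sample separately but not its animal, so p-values measure the spread between these samples.

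The engineered genes came first. Trp53 (chromosome 11, 69580348 to 69591873, GRCm38) was read at 2086, 1761, 1348 and 1039 in p53 KO 1 to 4, below the thymus libraries at 3214, 3393 and 3501. The fall passed (log2 fold change -1.16, adjusted p = 0.0164, SE 0.23) but ended without thymus 1, 2 or 3 (adjusted p up to 0.0907) and with only these groups fitted (0.0605), and the reads left do not check the deletion. Trp53 was higher than thymus in HrasG12V (7869 ± 837, adjusted p = 0.0223) and CIC LOF (5889.7 ± 1219.9, adjusted p = 0.0267), and both calls ended without thymus 1, 2 or 3, the first also without HrasG12V 1, 2 or 3 (adjusted p up to 0.110) and the second without CIC LOF 3, 4 or 5 (up to 0.0951), with quantile scaling (0.0705) or with CIC LOF 1 and 2 alone (0.390). Hras, listed as Hras1 (chromosome 7, 141189934 to 141194019), reached 2885, 1672 and 1496 in HrasG12V 1 to 3 and 919, 945 and 915 in thymus. The rise passed (log2 fold change 1.06, adjusted p = 0.0275) but ended without any 1 of the 6 libraries (adjusted p 0.0504 to 0.119). Kras (chromosome 6, 145216699 to 145250420), the locus that carries the transgene, averaged 1628 ± 127 in HrasG12V and 2929.9 ± 859 in thymus and passed in no comparison in the fit of all 15 samples. It passed as lower in HrasG12V with only these groups fitted, a fit free of p53 KO 1 (log2 fold change −0.80, adjusted p = 0.0293). It stood at 44858 in p53 KO 1 against 1306, 1873 and 2658 in p53 KO 2 to 4.

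Cic (chromosome 7, 25267658 to 25294159) was not lower in CIC LOF. Its level was 2962 and 2181 in CIC LOF 1 and 2 and 6713, 5861 and 6027 in CIC LOF 3 to 5, against 3830.3, 3989 and 4115 in thymus (log2 fold change 0.12, adjusted p = 0.810). It was 5246 ± 958 in HrasG12V and 3266 ± 808 in p53 KO. The labels do not name the deleted exons, and reads over the rest of the gene still count, so this level does not check the deletion. The estimate was −0.0330 without CIC LOF 3, and the gene passed as higher with array weights (adjusted p = 0.0285) and with CIC LOF 3 to 5 alone (0.0337), in a range over the alternatives of 0.0285 to 1. Etv4 (chromosome 11, 101769747 to 101785310), an ETS transcription factor gene repressed by CIC, was 1762, 2405 and 2580.4 in the LacZ carriers and 1912 and 2099 in CIC LOF 1 and 2. The remaining tumours had Etv4 levels of 629.9, 104 and 7.53 in HrasG12V 1 to 3 and 698, 42.8, 21.3 and 6.23 in p53 KO 1 to 4. Thymus held 36.3, 56.9 and 27.5.

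Thymus libraries resembled each other most, with Pearson's r across genes of 0.980 to 0.990 on log2 values, and p53 KO libraries least (0.852 to 0.908). HrasG12V pairs lay at 0.954 to 0.956 and CIC LOF pairs at 0.890 to 0.968. The first principal component held 38.1% of the variance and parted thymus (−122 to −114) from most tumours. CIC LOF 1 (−62.9) and p53 KO 2 (−104) lay nearest to thymus, and CIC LOF 3 to 5, the Etv4 LacZ carriers, lay farthest (82.6 to 127). The second component (17.1%) set p53 KO 1 (131) and p53 KO 3 (147) apart from all other libraries (at most 8.33).

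**Figure D1:**
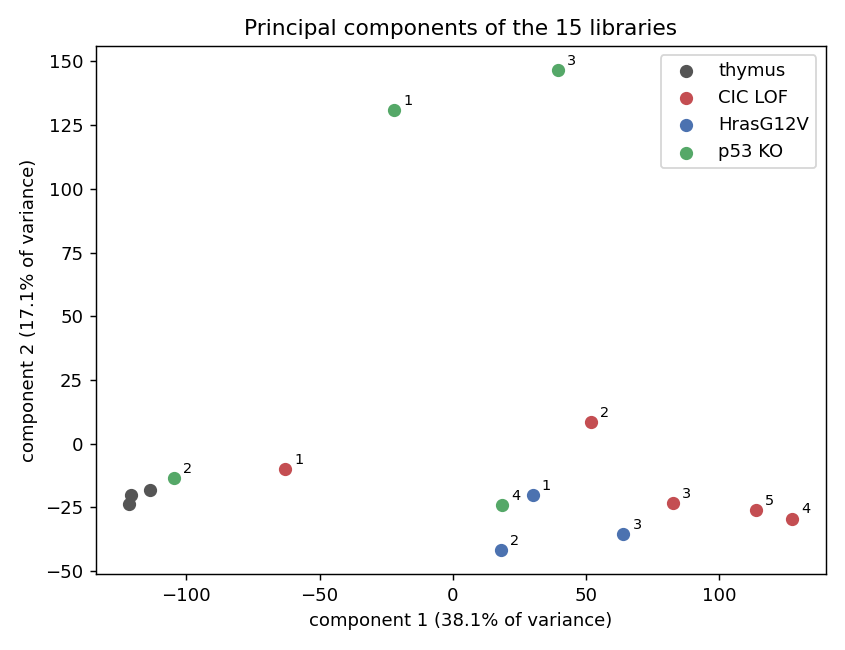
Principal components of log2 normalised values, with the first component (38.1% of variance) on the x axis and the second (17.1%) on the y axis and 1 point per library, coloured by group. CIC LOF 1 (−62.9) and p53 KO 2 (−104) lie between thymus (−122 to −114) and the other tumours on the first component.

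CIC LOF tumours were set against thymus to find what differs in them. Some genes that CIC represses rose. Etv4 rose from 40.2 ± 15.04 to 2152 ± 339 (log2 fold change 5.75, SE 1.30, adjusted p = 0.0113). Etv5, its close relative (chromosome 16, 22381313 to 22439570), rose as well (4023 ± 469 against 384 ± 18.1, log2 fold change 3.38, SE 0.62, adjusted p = 0.00582). Spry4, a feedback inhibitor of RAS-ERK signalling, was 517 ± 146 against 54.5 ± 12.5, log2 fold change 3.19, SE 0.61, adjusted p = 0.00704. Spred1, of the same family, was 1702 ± 444 against 513 ± 30.3, adjusted p = 0.00910. The DNA polymerase subunit Pole and the phosphatase Ptpn9 had log2 fold changes of 1.40 and 0.89 (adjusted p at most 0.0412). Of the CIC targets list, 6 of 19 rose, 0 fell and 13 did not pass (6 and 1 over the list alone), camera adjusted p = 0.0121, and 0.690 with estimated correlation. Without members shared with another list that call ended (0.159). Dusp6, another CIC target, was 1569 ± 661 against 1008 ± 102, adjusted p = 0.642, and Spry2 was 54.5 ± 55.1 against 185 ± 9.62, adjusted p = 0.0516. Etv5 and Spry4 passed without any 1 library. Etv4 ended without thymus 1 (adjusted p = 0.0509) or thymus 3 (0.0591), and Spred1 without thymus 2 (0.0514). Pole ended without thymus 1, 2 or 3 (up to 0.0603), and Ptpn9 without thymus 1, 2 or 3 or CIC LOF 3, 4 or 5 (up to 0.134). Ptpn9 also ended with quantile scaling (0.0531) and edgeR (0.0551). With CIC LOF 1 and 2 alone none of the 6 passed, with Etv4, Etv5 and Spry4 at 0.174, 0.126 and 0.148, and adjusted p over all alternatives ran from 1.52e-05 to 0.174 for Etv4.

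**Figure D2:**
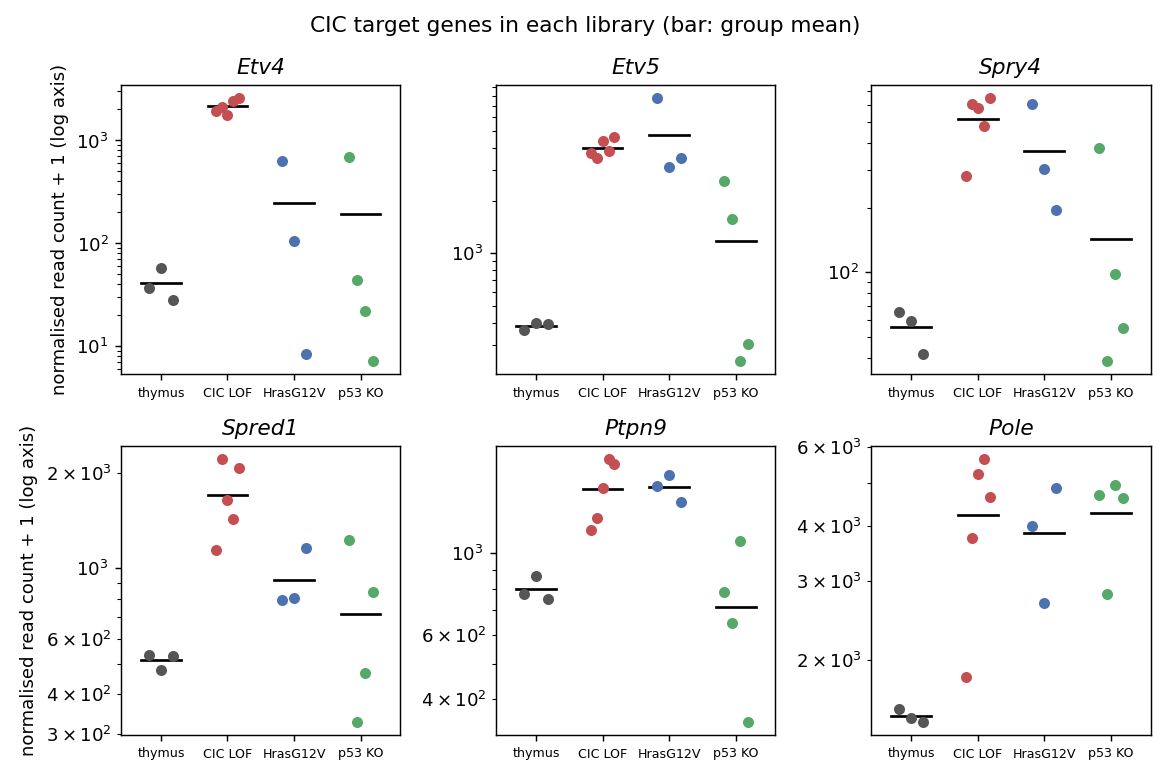
Normalised read counts (log axis) of Etv4, Etv5, Spry4, Spred1, Ptpn9 and Pole, with 1 point per library and a bar at each group mean. Etv4 lies between 1762 and 2580 in the 5 CIC LOF libraries and at 56.9 or below in thymus.

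Across all genes, 3334 changed between CIC LOF and thymus, 1409 higher and 1925 lower. The homeobox gene Dlx1 (chromosome 2, 71528113 to 71533981) rose most of the named genes (2981 ± 907 against 29.6 ± 28.8, log2 fold change 6.96, SE 1.15, adjusted p = 0.00428). Glp1r, the GLP-1 receptor, followed (149 ± 144 against 0.553 ± 0.479, adjusted p = 0.00397). Cbln1, the scavenger receptor Marco and the forkhead gene Foxb1 had log2 fold changes of 5.21, 5.06 and 4.92 (adjusted p at most 0.0152). Prss16, the thymus-specific serine protease of cortical epithelium, fell from 24006 ± 2647 to 797 ± 1747 (log2 fold change -9.75, adjusted p = 0.00736). The chemokine Ccl22 fell with it (83.3 ± 169.9 against 2164 ± 196, adjusted p = 0.00777). Tbata, Crip3, Ascl1 and Skint10 had log2 fold changes of -9.36, -7.72, -7.51 and -7.40 (adjusted p at most 0.0182). CIC LOF 1 held most of what remained, for example 3922 of Prss16 against 27.6, 30.5, 0 and 3.68 in CIC LOF 2 to 5. The samples of both groups did not overlap at 6387 genes (40.8%; chance gives 3.57%). The share higher was 42.3%, and 51.3% of 2689 with a filter at 50, 55.1% of 3175 calls after quantile normalisation, 54.6% of 2095 with edgeR and 58.0% of 3661 with DESeq2. The count was 701, 511 and 499 without thymus 1, 2 and 3 and 1862, 1868 and 1786 without CIC LOF 3, 4 and 5. It was 9697 with array weights, 24 with CIC LOF 1 and 2 alone, 5393 with CIC LOF 3 to 5 alone, and 5136 without CIC LOF 1 and p53 KO 2, a setting chosen after seeing the data. Without a thymus library Cbln1, Foxb1, Tbata, Crip3, Ascl1 and Skint10 did not pass (adjusted p up to 0.0730), while Dlx1, Glp1r, Marco, Prss16 and Ccl22 passed without any 1 library.

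Growth gene lists were higher in CIC LOF by camera. Of the MYC and ribosome biogenesis list, 24 of 24 rose, 0 fell and 0 did not pass (24 and 0 over the list alone), camera adjusted p = 3.88e-17, and 0.690 with estimated correlation. The nucleolar methyltransferase Fbl was 9438 ± 2006 against 3353 ± 43.3, log2 fold change 1.46, SE 0.23, adjusted p = 0.00397. Polr1b of RNA polymerase I and Nme1 had log2 fold changes of 1.81 and 1.20 (adjusted p at most 0.00398). Myc itself (chromosome 15, 61985341 to 61990361) rose to 8843 ± 2877 from 2451 ± 307 (log2 fold change 1.79, adjusted p = 0.00894). Of the cell cycle list, 20 of 30 rose, 0 fell and 10 did not pass (25 and 0 over the list alone), camera adjusted p = 4.65e-11, and 0.690 with estimated correlation. The spindle checkpoint kinase Bub1b was 11585 ± 1750.2 against 4232 ± 213, adjusted p = 0.00463. E2f1 and the ribonucleotide reductase Rrm1 had log2 fold changes of 1.46 and 1.05 (adjusted p at most 0.0126). Among glycolysis and hypoxia genes, 11 of 20 rose, 0 fell and 9 did not pass (11 and 0 over the list alone), camera adjusted p = 2.87e-06, and 0.690 with estimated correlation. Lactate dehydrogenase Ldha and the phosphofructokinase Pfkl had log2 fold changes of 1.64 and 1.79 (adjusted p at most 0.00546). The NOTCH feedback inhibitor Nrarp rose (1856 ± 967 against 275 ± 40.1, adjusted p = 0.00507) and the NOTCH target Hey1 fell (109 ± 109.9 against 512 ± 48.0, adjusted p = 0.0230). Of NOTCH targets 3 of 18 rose, 2 fell and 13 did not pass, or 3 and 2 over the list alone, camera adjusted p = 0.432. E2f1, Rrm1 and Hey1 did not pass without thymus 1, 2 or 3, nor Hey1 without CIC LOF 4 or 5 (adjusted p up to 0.0884). The other genes of this paragraph passed without any 1 library.

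Lists of later T cells and of the normal thymus were lower in CIC LOF by camera, and the mature T cell, epithelium and dendritic cell lists least so in CIC LOF 1 (scores −1.12, −1.11 and −0.06). Of the mature T cell list, 0 of 18 rose, 11 fell and 7 did not pass (0 and 15 over the list alone), camera adjusted p = 2.3e-05, and 0.690 with estimated correlation. Cd69, an activation marker, fell from 1488 ± 174 to 36.8 ± 25.6 (adjusted p = 0.00509). The lymph node homing receptor Ccr7 and S1pr1, which guides thymic exit, had log2 fold changes of -5.06 and -2.25 (adjusted p at most 0.00464). Of the double positive thymocyte list, 0 of 17 rose, 5 fell and 12 did not pass (0 and 5 over the list alone), camera adjusted p = 0.0111, and 0.771 with estimated correlation. The CD8 chain Cd8a fell (7432 ± 9092 against 42816 ± 1519, adjusted p = 0.0127). Cd8b1 and Themis had log2 fold changes of -3.53 and -1.48 (adjusted p at most 0.0260). Of thymic epithelium genes, 0 of 17 rose, 11 fell and 6 did not pass (0 and 12 over the list alone), camera adjusted p = 5.79e-06, and 0.690 with estimated correlation. They included the thymoproteasome subunit Psmb11 and the chemokine Ccl25, with log2 fold changes of -6.70 and -6.19 (adjusted p at most 0.00711). The MHC class II gene H2-Aa and its regulator Ciita had log2 fold changes of -3.09 and -2.99 (adjusted p at most 0.0240). In the dendritic cell and MHC class II list 0 of 14 rose, 7 fell and 7 did not pass (0 and 12 over the list alone), camera adjusted p = 0.000133, and 0.690 with estimated correlation. The Cd8a, Cd8b1, Themis, H2-Aa and Ciita calls ended without thymus 2 or 3, and all but Ciita without thymus 1. Themis ended also without CIC LOF 3, 4 or 5 and H2-Aa also without CIC LOF 4 or 5 (adjusted p up to 0.0955).

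The immediate early gene Egr1 fell in CIC LOF (235 ± 242 against 2635 ± 169, log2 fold change -3.93, SE 0.63, adjusted p = 0.00397). Nr4a1, induced by T cell receptor signals, was 259 ± 337 against 2007 ± 312, adjusted p = 0.00687. Egr2, Egr3 and Zfp36 had log2 fold changes of -3.88, -3.91 and -2.5 (adjusted p at most 0.00428). Of the MAPK output list, which shares Etv4, Etv5 and Spry4 with the CIC targets, 4 of 18 rose, 4 fell and 10 did not pass (4 and 5 over the list alone), camera adjusted p = 0.835. Its median (−0.003) and mean (−0.11) lay below 0 while camera's direction was upward. Of the handling stress genes, 0 of 16 rose, 3 fell and 13 did not pass (0 and 5 over the list alone), camera adjusted p = 0.0169, and 0.690 with estimated correlation. The p53 targets Aen, Ei24, Sesn1 and Trp53inp1 had log2 fold changes of 1.11, 0.90, -1.27 and -2.33 (adjusted p at most 0.0234). Of this list 4 of 28 rose, 4 fell and 20 did not pass, or 5 and 6 over the list alone, camera adjusted p = 0.866. The survival genes Bcl2 and Bcl2l1 had log2 fold changes of -1.94 and -1.66 (adjusted p at most 0.0401). Of apoptosis regulators 2 of 16 rose, 5 fell and 9 did not pass, or 2 and 5 over the list alone, camera adjusted p = 0.382. The Aen, Ei24, Trp53inp1, Bcl2 and Bcl2l1 calls ended without thymus 1, 2 or 3, Trp53inp1 and Bcl2l1 also without CIC LOF 3 or 5 and Bcl2l1 without CIC LOF 2 (adjusted p up to 0.120).

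The pericyte receptor Pdgfrb rose in CIC LOF (4372 ± 4255 against 425 ± 38.3, log2 fold change 2.87, SE 0.65, adjusted p = 0.0113), as did the collagen Col1a1 (10815 ± 8402 against 935 ± 578, adjusted p = 0.0218). The macrophage genes Cd68 and C1qb had log2 fold changes of 1.61 and 1.18 (adjusted p at most 0.0401). The granulocyte genes S100a8 and S100a9 had log2 fold changes of -6.01 and -6.09 (adjusted p at most 0.0113). Of fibroblast and stroma genes, 4 of 15 rose, 0 fell and 11 did not pass, or 4 and 0 over the list alone, camera adjusted p = 0.118. Of macrophage and granulocyte genes, 2 of 17 rose, 2 fell and 13 did not pass, or 6 and 2 over the list alone, camera adjusted p = 0.0230, and 0.834 with estimated correlation. Their scores were above thymus only in CIC LOF 1 and 2 (1.15 and 0.65). B cell genes (0 of 14 rose, 3 fell and 11 did not pass, or 0 and 3 over the list alone) gave camera adjusted p = 0.0140, and 0.799 with estimated correlation. For NK and gamma delta T cell genes, 0 of 14 rose, 1 fell and 13 did not pass, or 0 and 1 over the list alone, camera adjusted p = 0.0370, and 0.690 with estimated correlation. For interferon response genes, 0 of 22 rose, 1 fell and 21 did not pass, or 0 and 0 over the list alone, camera adjusted p = 0.0154, and 0.834 with estimated correlation, with scores of 0.05 and 0.13 in CIC LOF 1 and 3 and −2.59 to −1.78 in the others. The B cell, macrophage and NK calls ended with quantile scaling (0.0739, 0.166 and 0.0852), the NK call without a filter (0.0950) or with a pseudocount of 10 (0.0513), and the macrophage call with a filter at 50 (0.0612). Without CIC LOF 1 and p53 KO 2 the macrophage and double positive calls ended (0.149 and 0.0667). The endothelium, adipocyte, erythroid, double negative and T-ALL lists were not called (0.219, 0.769, 0.465, 0.482 and 0.994). For the T-ALL list the median (−0.13) and mean (−0.35) lay below 0 and camera's direction was upward. Pdgfrb did not pass without thymus 2 or 3, Col1a1 and C1qb without any 1 thymus or CIC LOF 3 or 5, and C1qb also without CIC LOF 1 or 2. S100a8 did not pass without thymus 1 or 2, and S100a9 without thymus 2 (adjusted p up to 0.121).

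HrasG12V tumours were set against thymus to describe T-ALL driven by an oncogenic RAS. Among CIC-repressed genes Etv5, Spry4 and Pole were called higher, as in CIC LOF, and Etv4 was not, but the difference in Etv4 between HrasG12V and CIC LOF did not pass either (adjusted p = 0.124; 0.0168 with array weights). Etv5 rose (4779 ± 2570.4 against 384 ± 18.1, log2 fold change 3.51, SE 0.69, adjusted p = 0.0214), as did Spry4 (366 ± 214 against 54.5 ± 12.5, adjusted p = 0.0452). Spred3 and Pole had log2 fold changes of 2.66 and 1.32 (adjusted p at most 0.0497). Etv4 was 247 ± 335 against 40.2 ± 15.04, adjusted p = 0.668, carried by HrasG12V 1 (629.9) and at 7.53 in HrasG12V 3, and its estimate turned to −0.40 without HrasG12V 1. Spred1 (920.0 ± 208 against 513 ± 30.3, adjusted p = 0.199) and Ptpn9 (1514 ± 131 against 796 ± 60.1, adjusted p = 0.0914) did not pass, but did with only these groups fitted (0.0118 and 0.00185). Of the CIC targets list, 4 of 19 rose, 0 fell and 15 did not pass (6 and 0 over the list alone), camera adjusted p = 0.00268, and 0.690 with estimated correlation. Of MAPK output, 3 of 18 rose, 1 fell and 14 did not pass, or 3 and 2 over the list alone, camera adjusted p = 0.462. Its member Epha4, a receptor, fell (10.7 ± 2.42 against 79.5 ± 14.2, adjusted p = 0.0327). All of these calls ended without any 1 thymus library or HrasG12V 1 or 3, and all but Etv5 without HrasG12V 2 (adjusted p up to 0.164 for Pole). Pole also ended with a pseudocount of 0.5 (0.0525), a filter at 50 (0.0542), a robust prior (0.0504) and edgeR (0.0648), and Spry4 with edgeR (0.0722).

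Of all genes, 810 changed between HrasG12V and thymus, 324 higher and 486 lower. The zinc finger gene Sall3 rose most of the named genes (2364 ± 523 against 5.31 ± 5.71, log2 fold change 8.90, SE 2.17, adjusted p = 0.0349), and the transporter Slc45a3 rose too (2241 ± 963 against 104 ± 22.1, adjusted p = 0.00604). Foxb1, the lectin Cd209g, Wdr25 and Tox2 had log2 fold changes of 5.90, 5.32, 5.21 and 4.87 (adjusted p at most 0.0464). Prss16 fell most of them (15.8 ± 6.99 against 24006 ± 2647, adjusted p = 0.0224), and the CD40 ligand Cd40lg fell as well (1.14 ± 1.09 against 284 ± 46.7, adjusted p = 0.0179). Psmb11, the neurofilament Nefm, Zcchc12 and Ccl25 had log2 fold changes of -8.20, -7.69, -7.10 and -6.98 (adjusted p at most 0.0230). The groups did not overlap at 8969 genes (57.3%; chance gives 10%). Higher genes made up 40% of the calls, and 51.3% of 532 with a filter at 50, 52.6% of 1246 after quantile normalisation and 56.6% of 221 with edgeR; DESeq2 called 2045. The count fell to 17, 9 and 7 without thymus 1, 2 and 3 and to 66, 184 and 23 without HrasG12V 1, 2 and 3. It was 6263 with only these groups fitted, 6821 with array weights, 1392 with a pseudocount of 10, 1502 without a filter and 2406 without CIC LOF 1 and p53 KO 2. Of the 35 named genes that passed, Slc45a3 passed in each fit without 1 library, and without thymus 1, 2 or 3 33, 34 and 34 of the 35 did not.

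Myc rose in HrasG12V (9244 ± 995 against 2451 ± 307, adjusted p = 0.0276). Of MYC and ribosome biogenesis genes, 7 of 24 rose, 0 fell and 17 did not pass (21 and 0 over the list alone), camera adjusted p = 2.11e-11, and 0.690 with estimated correlation. Cad of pyrimidine synthesis and Nme1 had log2 fold changes of 1.85 and 0.87 (adjusted p at most 0.0307). Of glycolysis and hypoxia genes, 8 of 20 rose, 0 fell and 12 did not pass (13 and 0 over the list alone), camera adjusted p = 1.43e-06, and 0.690 with estimated correlation. They included Gapdh and the pyruvate kinase Pkm, listed as Pkm2, with log2 fold changes of 1.46 and 1.92 (adjusted p at most 0.0310). No cell cycle gene passed alone (0 of 30 passed, or 0 and 0 over the list alone) although the list did, camera adjusted p = 3.73e-05, and 0.690 with estimated correlation, with HrasG12V 2 at the thymus level (−0.01, against 0.70 and 0.85). NOTCH targets (2 of 18 rose, 1 fell and 15 did not pass, or 4 and 1 over the list alone) gave camera adjusted p = 0.0244, and 0.690 with estimated correlation. Hey1 fell (21.9 ± 5.97 against 512 ± 48.0, adjusted p = 0.0198). Mature T cell genes (0 of 18 rose, 3 fell and 15 did not pass, or 0 and 5 over the list alone) gave camera adjusted p = 0.0150, and 0.690 with estimated correlation. S1pr1 fell (172 ± 43.9 against 1124 ± 203, adjusted p = 0.00918). The regulatory T cell factor Foxp3 and Ms4a4b had log2 fold changes of -5.22 and -4.87 (adjusted p at most 0.0254). Thymic epithelium (0 of 17 rose, 6 fell and 11 did not pass, or 0 and 9 over the list alone) gave camera adjusted p = 2.87e-06, and 0.690 with estimated correlation. The NOTCH and cell cycle calls ended with quantile scaling (0.0628 and 0.0587), NOTCH with a filter at 50 (0.0687) and mature T cell without a filter (0.0580). Each gene call here ended without at least thymus 2 or 3 and HrasG12V 3 (adjusted p up to 0.127 for Pkm2).

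B cell genes were lower in HrasG12V (0 of 14 rose, 2 fell and 12 did not pass, or 0 and 6 over the list alone), camera adjusted p = 0.000150, and 0.690 with estimated correlation. The CD20 gene Ms4a1 fell (23.3 ± 35.2 against 233 ± 9.71, adjusted p = 0.0330). Interferon response genes (0 of 22 rose, 1 fell and 21 did not pass, or 0 and 4 over the list alone) gave camera adjusted p = 4.05e-05, and 0.690 with estimated correlation. The signal transducer Stat2 fell (1399 ± 332 against 2424 ± 123, adjusted p = 0.0495). Dendritic cell and MHC class II genes (0 of 14 passed, or 0 and 2 over the list alone) gave camera adjusted p = 0.000620, and 0.707 with estimated correlation. Pdgfrb and Cd68 had log2 fold changes of 4.14 and 1.83 (adjusted p at most 0.0171). The CD4 co-receptor Cd4 fell (2392 ± 993 against 20918 ± 494, adjusted p = 0.0362), while the double positive thymocyte list did not pass (camera adjusted p = 0.0620; 0.0383 without shared members). The p53 targets Bax, a death effector, and Sesn1 had log2 fold changes of 1.22 and -0.83 (adjusted p at most 0.0366). Of the list 2 of 28 rose, 1 fell and 25 did not pass, or 3 and 1 over the list alone, camera adjusted p = 0.734. That list's median (−0.05) and mean (−0.18) lay below 0 with camera's direction upward. The Ms4a1, Stat2, Pdgfrb, Cd68, Cd4, Bax and Sesn1 calls ended without thymus 1, 2 or 3 and without HrasG12V 3 (adjusted p up to 0.173).

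In p53 KO tumours Cdkn2a, which encodes the tumour suppressors p16 and ARF (chromosome 4, 89274473 to 89294619), rose most of all named genes. It went from 50.2 ± 7.12 in thymus to 6163 ± 3218 (log2 fold change 6.76, SE 0.70, adjusted p = 0.00182) and passed without any 1 library (adjusted p at most 0.0186). Among p53 targets Mdm2, the p53 ubiquitin ligase, fell (1899 ± 396 against 3067 ± 81.3, adjusted p = 0.0263), as did the stress sensor Sesn1 (1665 ± 389 against 2946 ± 192, adjusted p = 0.0238). Of that list, 0 of 28 rose, 2 fell and 26 did not pass (0 and 11 over the list alone), camera adjusted p = 0.0303, and 0.690 with estimated correlation. CIC-repressed genes were mostly not called, with Etv5 at 1179.8 ± 1129 against 384 ± 18.1, adjusted p = 0.376. Spry4 was 142 ± 160.0 against 54.5 ± 12.5, adjusted p = 0.463, and Etv4 was 192 ± 338 against 40.2 ± 15.04, adjusted p = 0.926. Pole rose (4265 ± 977 against 1492 ± 49.7, adjusted p = 0.0247). Of the CIC targets list, 1 of 19 rose, 0 fell and 18 did not pass (1 and 0 over the list alone), camera adjusted p = 0.688, with a median of 0.25 and a mean of −0.01. p53 KO 1 carried most of the Etv4 signal, and without it the Etv4 estimate was −1.04. The Mdm2, Sesn1 and Pole calls ended without thymus 1, 2 or 3 or p53 KO 3 (adjusted p up to 0.120).

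Between p53 KO and thymus 934 genes changed, 557 higher and 377 lower. After Cdkn2a the highest was Tox2 (2922 ± 3752 against 64.0 ± 25.1, log2 fold change 4.74, SE 1.06, adjusted p = 0.0228), and the lactate exporter Slc16a3 rose too (2163 ± 2324 against 101 ± 8.17, adjusted p = 0.0168). Enthd1, the muscarinic receptor Chrm4 and the small GTPase Rem2 had log2 fold changes of 4.39, 4.11 and 3.94 (adjusted p at most 0.0202). The lowest was Psmb11 (28.6 ± 27.1 against 3335 ± 485, adjusted p = 0.0112), followed by Pax1 of the thymic epithelium (116 ± 199 against 2952 ± 320.1, adjusted p = 0.0495). Plekhb1, Fgf14, Ccl25 and Snap91 had log2 fold changes of -6.42, -6.19, -5.90 and -5.82 (adjusted p at most 0.0496). The groups did not overlap at 4390 genes (28.1%; chance gives 5.71%). Higher genes made up 59.6% of the calls, and 70.6% of 708 with edgeR and 70.5% of 2034 with DESeq2. The balance turned without p53 KO 2 (40.2% of 2078), without CIC LOF 1 and p53 KO 2 (41.2% of 2707), without a filter (46.3% of 1228) and with a pseudocount of 10 (49.4% of 1294). The count was 6, 4 and 3 without thymus 1, 2 and 3, and 2078 and 458 without p53 KO 2 and 3. It was 215 with only these groups fitted, 2117 with array weights, 1702 with quantile scaling and 600 with a 2-fold minimum. Without CIC LOF 1 and p53 KO 2 it was 2707, and without p53 KO 1 and 3, also chosen after seeing the data, 666. Of the 31 named genes that passed, 30 did not pass without thymus 1, thymus 2 or thymus 3.

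Of MYC and ribosome biogenesis genes, 13 of 24 rose, 0 fell and 11 did not pass (21 and 0 over the list alone), camera adjusted p = 2.2e-15, and 0.690 with estimated correlation. The spermidine synthase Srm and Nme1 had log2 fold changes of 2.08 and 1.09 (adjusted p at most 0.0186). Of glycolysis and hypoxia genes, 9 of 20 rose, 0 fell and 11 did not pass (12 and 0 over the list alone), camera adjusted p = 2.87e-06, and 0.690 with estimated correlation. Ldha rose (37167 ± 10580.1 against 13221 ± 227, adjusted p = 0.0132). Aldoa and the glucose transporter Slc2a1 had log2 fold changes of 1.72 and 1.45 (adjusted p at most 0.0114). Cell cycle genes (1 of 30 rose, 0 fell and 29 did not pass, or 0 and 0 over the list alone) gave camera adjusted p = 5.25e-05, and 0.690 with estimated correlation. Cdc20 was 7015 ± 2700.0 against 2875 ± 38.1, adjusted p = 0.0407. The double positive thymocyte list was lower (0 of 17 rose, 3 fell and 14 did not pass, or 0 and 4 over the list alone), camera adjusted p = 5.92e-05, and 0.690 with estimated correlation. It was lowest in p53 KO 1 and 3 (scores −3.83 and −5.55, against −1.09 and −0.22 in p53 KO 2 and 4). Cd4 fell (3676 ± 3528 against 20918 ± 494, adjusted p = 0.0315). Cd1d1 and Themis had log2 fold changes of -1.38 and -1.83 (adjusted p at most 0.0270). Mature T cell genes (0 of 18 rose, 2 fell and 16 did not pass, or 0 and 2 over the list alone) gave camera adjusted p = 0.00358, and 0.690 with estimated correlation. Bcl2 and S1pr1 had log2 fold changes of -2.31 and -1.77 (adjusted p at most 0.0224). Thymic epithelium (0 of 17 rose, 4 fell and 13 did not pass, or 0 and 11 over the list alone) gave camera adjusted p = 7.59e-07, and 0.690 with estimated correlation. Ly75 was 867 ± 402 against 2431 ± 129.7, adjusted p = 0.0317. The endothelial list was higher (1 of 15 rose, 0 fell and 14 did not pass, or 1 and 0 over the list alone), camera adjusted p = 0.00611, and 0.690 with estimated correlation, again mainly in p53 KO 1 and 3 (1.01 and 1.06, against 0.35 and 0.08). Egfl7 was 637 ± 26.2 against 261 ± 36.7, adjusted p = 0.0332. Interferon response genes (0 of 22 passed, or 0 and 0 over the list alone) gave camera adjusted p = 0.0347, and 0.834 with estimated correlation, with p53 KO 4 lowest (−2.33, against −0.83 to 0.33). It ended without a filter (0.0878), as did the p53 targets call (0.0835). Bcl2l1 and Egr2 had log2 fold changes of -2.30 and -2.99 (adjusted p at most 0.0281). None of the genes named here passed without thymus 1, 2 or 3, and Cd4, Cd1d1, Themis, Cdc20, Egfl7, Bcl2l1 and Egr2 did not pass without p53 KO 3 either (adjusted p up to 0.1502).

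**Figure D3:**
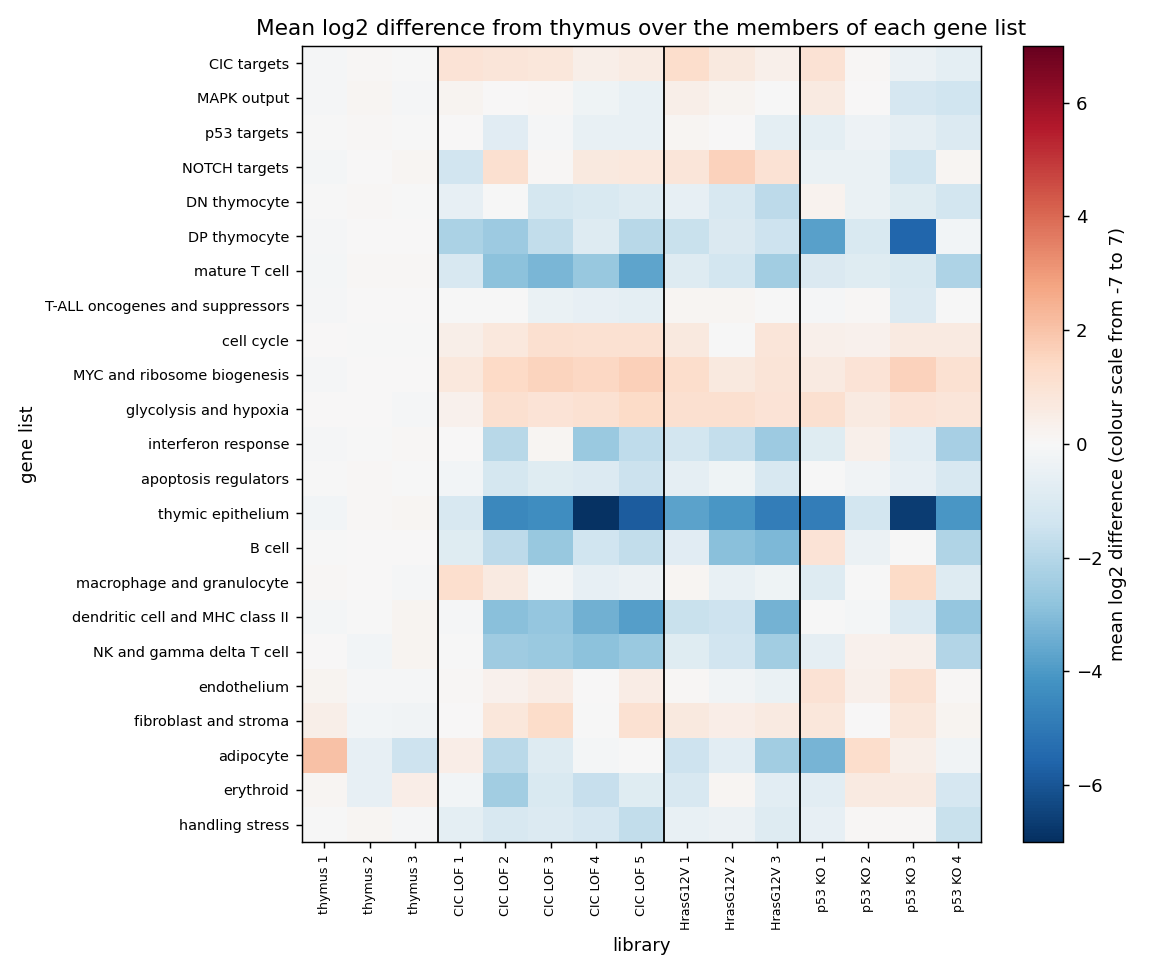
Heat map of each gene list (y axis) in each library (x axis), as the mean log2 difference of its members from the thymus mean, on a colour scale from −7 to 7. The NK and gamma delta T cell score is −0.008 in CIC LOF 1 and −2.88 to −2.49 in CIC LOF 2 to 5.

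Median, mean and camera's direction differed in sign for other lists without a call. Against thymus these were macrophage and granulocyte genes in HrasG12V and p53 KO and erythroid genes in p53 KO. Others were apoptosis, adipocyte and T-ALL (CIC LOF against p53 KO), macrophage, apoptosis and epithelium (HrasG12V against p53 KO), epithelium and glycolysis (CIC LOF against HrasG12V) and apoptosis, adipocyte and erythroid lists (Etv4 split).

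In calls against thymus CIC LOF and HrasG12V shared 244 higher and 401 lower genes (29.2 and 59.8 expected of independent lists). CIC LOF and p53 KO shared 370 higher and 245 lower (50.2 and 46.4 expected), and HrasG12V and p53 KO 119 and 128 (11.5 and 11.7). All 3 tumour types shared 103 higher and 121 lower genes, among them Psmb11, Ccl25, S1pr1, Sesn1, Nme1 and Pole. Few can remain without thymus 2 or 3, where p53 KO had 4 or 3 calls and HrasG12V 9 or 7. Log2 fold changes correlated across genes, which are not independent replicates, at r = 0.81, 0.70 and 0.68 in the same order. Unchanged groups and thymus, all simulated 20 times, gave 0.56, 0.60 and 0.53, and shared on average 0 to 0.05 calls, having few to share. The covariances were 1.61, 1.15 and 1.06 against 0.26 simulated for each. The 3 thymus libraries could not be split into parts of at least 2, so shared controls may add to the excess.

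CIC LOF differed from p53 KO in some genes that CIC represses, in Trp53 and in Cdkn2a. Etv4 was higher in CIC LOF (2152 ± 339 against 192 ± 338, log2 fold change 5.50, SE 1.19, adjusted p = 0.0242), as was Etv5 (4023 ± 469 against 1179.8 ± 1129, adjusted p = 0.0299). Spry4, Spred1, Ptpn9 and the ETS gene Etv1 had log2 fold changes of 2.40, 1.39, 1.16 and 2.53 (adjusted p at most 0.0325). Of the CIC targets list, 6 of 19 rose, 0 fell and 13 did not pass (8 and 0 over the list alone), camera adjusted p = 0.00782, and 0.690 with estimated correlation. The score of p53 KO 1 (0.99) lay above all 5 CIC LOF libraries (0.40 to 0.95), and p53 KO 2 to 4 (0.07, −0.40 and −0.71) made the difference. Without members shared with another list the call ended (0.222, median −0.08). Trp53 was higher in CIC LOF (5889.7 ± 1219.9 against 1559 ± 459.7, adjusted p = 0.000569) and Cdkn2a lower (116 ± 115 against 6163 ± 3218, log2 fold change -6.15, SE 0.61, adjusted p = 0.000569). Both passed without any 1 library, but Trp53 not with CIC LOF 1 and 2 alone (0.0518). The p53 targets Eda2r and Ei24 had log2 fold changes of 3.05 and 1.04 (adjusted p at most 0.0212). Of that list 2 of 28 rose, 0 fell and 26 did not pass (4 and 0 over the list alone), camera adjusted p = 0.0244, and 0.690 with estimated correlation. Etv4 did not pass without CIC LOF 3 (adjusted p = 0.0537), 4 (0.0506) or 5 (0.0599), with edgeR (0.0972), with only these groups fitted (0.0694) or with CIC LOF 1 and 2 alone (0.231), over a range of 0.00685 to 0.231. Etv5, Spry4, Spred1 and Ptpn9 ended with only these groups fitted (0.133, 0.133, 0.144 and 0.144) and with CIC LOF 1 and 2 alone, and Etv5 and Spry4 with edgeR (0.0739 and 0.0775). The other CIC target calls all ended without CIC LOF 3 or 5 (adjusted p up to 0.0767), as did Ei24 (0.0563). Etv5, Spry4, Spred1 and Ptpn9 also ended without CIC LOF 4, and Spry4, Spred1 and Etv1 without CIC LOF 2. Further losses came without p53 KO 1 (Etv1), p53 KO 2 (Spry4 and Spred1) and p53 KO 3 (Etv5, Spred1 and Etv1).

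Between CIC LOF and p53 KO 876 genes changed, 392 higher in CIC LOF and 484 lower. Dlx1 was the highest (2981 ± 907 against 9.28 ± 13.8, log2 fold change 9.17, SE 1.06, adjusted p = 0.000876). Stmn1-rs1, Cbln1, the glucose transporter family member Slc5a9 and Dlx2 had log2 fold changes of 7.47, 6.34, 4.74 and 4.64 (adjusted p at most 0.0346). The chemokine receptor Ccr8 was the lowest (2.65 ± 4.63 against 825 ± 1367, adjusted p = 0.00386), and Pacsin1 had the lowest p (12.2 ± 5.37 against 794 ± 278, log2 fold change -5.95, SE 0.37, adjusted p = 2.5e-06). Raver2, Nrn1 and the zinc finger gene Prdm16 had log2 fold changes of -6.31, -6.27 and -5.91 (adjusted p at most 0.00990). The groups did not overlap at 865 genes (5.53%; chance gives 1.59%). Higher genes made up 44.7% of calls and 33.8% of 1159 with edgeR; DESeq2 called 2387. The count was 2113, 186, 283 and 221 without CIC LOF 1, 3, 4 and 5 and 399 and 1654 without p53 KO 1 and 4. It was 28 with only these groups fitted, 10 with CIC LOF 1 and 2 alone, 2590 with CIC LOF 3 to 5 alone, 1685 without CIC LOF 1 and p53 KO 2 and 544 without p53 KO 1 and 3. Slc5a9 did not pass without p53 KO 1 or CIC LOF 2, 3, 4 or 5 and Dlx2 without p53 KO 1, 2 or 3 (adjusted p up to 0.0840). The other 8 genes of this paragraph passed without any 1 library.

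Camera also called other lists between CIC LOF and p53 KO, but for all 9 called lists the library scores of both groups overlapped. Nrarp was higher (1856 ± 967 against 301 ± 105, log2 fold change 2.5, SE 0.41, adjusted p = 0.00728). The kinase gene Jak1 was lower (6222 ± 715 against 13127 ± 2921, adjusted p = 0.00668) and Etv6 higher (2739.6 ± 508 against 1523 ± 431, adjusted p = 0.0344). Cell cycle genes were higher (3 of 30 rose, 0 fell and 27 did not pass, or 5 and 0 over the list alone), camera adjusted p = 3.03e-05, and 0.690 with estimated correlation. Bub1b, E2f1 and Rrm1 had log2 fold changes of 1.17, 1.22 and 0.82 (adjusted p at most 0.0443). Mature T cell genes were lower (0 of 18 rose, 2 fell and 16 did not pass, or 0 and 5 over the list alone), camera adjusted p = 0.00986, and 0.690 with estimated correlation. The gut homing integrin Itgb7 and Cd69 had log2 fold changes of -4.09 and -3.35 (adjusted p at most 0.0452). Handling stress genes were lower (0 of 16 rose, 3 fell and 13 did not pass, or 0 and 4 over the list alone), camera adjusted p = 0.0244, and 0.715 with estimated correlation, which ended without shared members (0.0505). Egr1, Zfp36 and Nr4a1 had log2 fold changes of -2.31, -1.47 and -2.64 (adjusted p at most 0.0365). The mannose receptor Mrc1 of macrophages was higher (4758 ± 4224 against 843 ± 908, adjusted p = 0.0486). B cell, dendritic cell and MHC class II, and NK and gamma delta T cell genes were lower by camera, though p53 KO 4 (−2.11, −2.70 and −2.04) lay among or near CIC LOF 2 to 5 and CIC LOF 1 (−0.83, −0.06 and −0.008) above them. Of B cell genes 0 of 14 passed, or 0 and 4 over the list alone, camera adjusted p = 0.00531, and 0.755 with estimated correlation. Of dendritic cell and MHC class II genes 0 of 14 passed, or 0 and 5 over the list alone, camera adjusted p = 0.000620, and 0.707 with estimated correlation. Of NK and gamma delta T cell genes 0 of 14 passed, or 0 and 3 over the list alone, camera adjusted p = 0.0344, and 0.690 with estimated correlation. MYC and ribosome biogenesis (0 of 24 passed, or 0 and 0 over the list alone) gave camera adjusted p = 0.00467, and 0.799 with estimated correlation. The MYC and NK calls ended with quantile scaling (0.0620 and 0.0528), p53 targets with a filter at 50 (0.109), and p53 targets and handling stress without CIC LOF 1 and p53 KO 2 (0.0573 and 0.163). Nrarp, Jak1 and Bub1b passed without any 1 library. The other genes named here did not pass without CIC LOF 3, and Mrc1 did not in 8 of 9 such fits (adjusted p up to 0.130).

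HrasG12V differed from p53 KO at 112 genes, 59 higher and 53 lower. Trp53 was higher (7869 ± 837 against 1559 ± 459.7, log2 fold change 2.38, SE 0.23, adjusted p = 0.000853). Hras1 was higher (2017 ± 756 against 968 ± 114, adjusted p = 0.0496) and Cdkn2a lower (309.7 ± 92.5 against 6163 ± 3218, adjusted p = 0.0219). The relaxin receptor Rxfp1 had no read in any p53 KO library and 279, 147 and 108 in HrasG12V 1 to 3, at least 52.9-fold higher against a floor of 3 counts per library. Cd209g, the IL-12 receptor chain Il12rb2, Cd209f and Slc45a3 were also higher, with log2 fold changes of 6.08, 4.63, 4.35 and 4.00 (adjusted p at most 0.0401). Prdm16 was the lowest (8.05 ± 9.13 against 910.4 ± 469, adjusted p = 0.00107). Raver2, Crmp1, Uchl1, the metalloprotease Adam12 and the atypical protein kinase C Prkcz had log2 fold changes of -6.21, -5.59, -5.12, -4.30 and -4.28 (adjusted p at most 0.0401). Groups did not overlap at 2127 genes (13.6%; chance gives 5.71%). Higher genes were 52.7% of calls and 36.4% of 1448 with DESeq2, and 42.0% of 81 and 44.2% of 86 without p53 KO 1 and 3; edgeR called 60, array weights 22, no filter 52 and a fit of only these groups 6. The count was 34, 17 and 14 without HrasG12V 1, 2 and 3 and 173 and 975 without p53 KO 2 and 4, and 399 without CIC LOF 1 and p53 KO 2. Only Trp53, Rxfp1, Prdm16 and Uchl1 of the 14 genes named here passed in each of these fits without 1 library, and Cd209g and Slc45a3 missed the threshold only without HrasG12V 3 (0.0650 and 0.0506). The other 8 ended without any 1 HrasG12V library, and Hras1, Cd209f, Raver2 and Crmp1 also without p53 KO 1 or 3 (adjusted p up to 0.159). Hras1 also ended with only these groups fitted (0.284), array weights (0.105), no filter (0.0612), quantile scaling (0.0579), edgeR (0.0523), a pseudocount of 0.5 (0.0510) and without p53 KO 1 and 3 (0.148).

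Between HrasG12V and p53 KO camera called 9 lists, and library scores overlapped in all but the NOTCH and endothelium lists. No CIC target passed over all genes (0 of 19 passed, or 3 and 0 over the list alone). Etv5 was 4779 ± 2570.4 against 1179.8 ± 1129, adjusted p = 0.0746, and Etv4 was 247 ± 335 against 192 ± 338, adjusted p = 0.788. Etv5 passed with DESeq2 (0.0215), without p53 KO 1 (0.0270) and without CIC LOF 1 and p53 KO 2 (0.0458). Ptpn9 passed with DESeq2 (0.0127), without p53 KO 3 (0.0411) or 4 (0.0394) and without p53 KO 1 and 3 (0.0298). That list gave camera adjusted p = 0.00106, and 0.690 with estimated correlation, with p53 KO 1 (0.99) among HrasG12V (0.35 to 1.21). The p53 targets were higher (1 of 28 rose, 0 fell and 27 did not pass, or 6 and 1 over the list alone), camera adjusted p = 0.00128, and 0.690 with estimated correlation, in HrasG12V 1 and 2 only (0.15 and 0.02), with HrasG12V 3 (−0.70) below p53 KO 1 to 3 (−0.69 to −0.34). The repair gene Ercc5 was 1239.8 ± 346 against 549.6 ± 90.8, adjusted p = 0.0392. NOTCH targets (0 of 18 passed, or 2 and 0 over the list alone) gave camera adjusted p = 0.00214, and 0.690 with estimated correlation. B cell genes were lower (0 of 14 rose, 1 fell and 13 did not pass, or 0 and 2 over the list alone), camera adjusted p = 2.76e-05, and 0.690 with estimated correlation. Fcrla was 13.9 ± 13.8 against 176 ± 119, adjusted p = 0.0430. Endothelial genes were lower (0 of 15 passed, or 0 and 6 over the list alone), camera adjusted p = 0.000102, and 0.690 with estimated correlation. MAPK output (0 of 18 passed, or 1 and 0 over the list alone) was higher, camera adjusted p = 0.0315, and 0.690 with estimated correlation, but p53 KO 1 (0.65) lay above all HrasG12V libraries (−0.05 to 0.44), and p53 KO 3 and 4 (−1.15 and −1.37) made the call. Without members shared with another list, among them CIC targets, it ended (0.741, median −0.03). Double positive thymocyte genes (0 of 17 passed, or 0 and 0 over the list alone) were higher, camera adjusted p = 0.0319, and 0.799 with estimated correlation, a difference made by p53 KO 1 and 3 that ended without shared members (0.0588). Interferon response genes (0 of 22 passed, or 0 and 0 over the list alone) were lower, camera adjusted p = 0.0104, and 0.834 with estimated correlation. Dendritic cell and MHC class II genes (0 of 14 passed, or 0 and 0 over the list alone) were lower, camera adjusted p = 0.0118, and 0.799 with estimated correlation. In the B cell, interferon and dendritic cell lists p53 KO 4 (−2.11, −2.33 and −2.70) lay within the HrasG12V range. MAPK output and double positive calls ended with a filter at 50 (0.1004 and 0.0650) or only these groups fitted (0.0840 and 0.0711), double positive with quantile scaling (0.0626) and interferon without CIC LOF 1 and p53 KO 2 (0.192). Ercc5 did not pass without p53 KO 1 or HrasG12V 1 or 2 and Fcrla without p53 KO 1, 2 or 3 or HrasG12V 2 or 3 (adjusted p up to 0.171).

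CIC LOF and HrasG12V differed at 128 genes, 21 higher in CIC LOF and 107 lower. Dlx1 was higher in CIC LOF (2981 ± 907 against 107 ± 115, log2 fold change 5.97, SE 1.15, adjusted p = 0.0262). Glp1r, Ptprn2, Zfp532, Sestd1 and Oaf had log2 fold changes of 5.08, 4.92, 3.38, 2.89 and 2.86 (adjusted p at most 0.0488). The alkaline phosphatase Alpl was lower (16.7 ± 4.51 against 809.8 ± 267, log2 fold change -5.51, SE 0.73, adjusted p = 0.00484). Iqch, the potassium channel Kcnf1, Tox2, the kinase Hunk and Fgf13 had log2 fold changes of -6.09, -5.85, -5.81, -5.65 and -5.60 (adjusted p at most 0.0469). The groups did not overlap at 1375 genes (8.79%; chance gives 3.57%). Higher genes were 16.4% of calls and 37.5% of 594 with DESeq2. The count was 200, 44 and 61 without CIC LOF 1, 3 and 5 and 50, 10 and 24 without HrasG12V 1, 2 and 3. It was 1306 with array weights, 50 with CIC LOF 1 and 2 alone, 374 with CIC LOF 3 to 5 alone and 310 without CIC LOF 1 and p53 KO 2. Of the 18 named genes Alpl alone passed in each fit without 1 library (adjusted p at most 0.0460), and without HrasG12V 2 or 3 the other 17 did not.

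For all 7 lists called between CIC LOF and HrasG12V library scores overlapped. CIC targets were not called (0 of 19 rose, 1 fell and 18 did not pass, or 1 and 1 over the list alone; camera adjusted p = 0.757). Etv4 was 2152 ± 339 against 247 ± 335, log2 fold change 4.69, SE 1.30, adjusted p = 0.124, which did not pass, and Etv5 was 4023 ± 469 against 4779 ± 2570.4, adjusted p = 0.964. Spred3 was lower in CIC LOF (57.9 ± 27.5 against 329 ± 112, adjusted p = 0.0347). The immediate early genes Egr1 and Nr4a1 had log2 fold changes of -3.01 and -3.50 (adjusted p at most 0.0405). Handling stress genes (0 of 16 rose, 2 fell and 14 did not pass, or 0 and 5 over the list alone) gave camera adjusted p = 0.0409, and 0.762 with estimated correlation, which ended without shared members (0.114). L-selectin, Sell, was lower (1040.3 ± 885 against 16217 ± 5363, adjusted p = 0.0182). Mature T cell genes (0 of 18 rose, 1 fell and 17 did not pass, or 0 and 7 over the list alone) gave camera adjusted p = 0.00304, and 0.690 with estimated correlation. Jak1 was lower (6222 ± 715 against 12234 ± 2179, adjusted p = 0.0245), and Odc1 of polyamine synthesis was higher (13302 ± 6231 against 4305 ± 1750.4, adjusted p = 0.0458). MYC and ribosome biogenesis (1 of 24 rose, 0 fell and 23 did not pass, or 1 and 0 over the list alone) gave camera adjusted p = 3.91e-06, and 0.690 with estimated correlation. Cell cycle genes (0 of 30 passed, or 0 and 0 over the list alone) gave camera adjusted p = 1.33e-05, and 0.690 with estimated correlation. Interferon response genes (0 of 22 passed, or 0 and 0 over the list alone) were higher in CIC LOF, camera adjusted p = 0.0304, and 0.834 with estimated correlation. Only CIC LOF 1 and 3 (0.05 and 0.13) lay above the HrasG12V range (−2.57 to −1.31), with −1.93, −2.59 and −1.78 in CIC LOF 2, 4 and 5. Endothelium (0 of 15 passed, or 0 and 0 over the list alone) was higher, camera adjusted p = 0.00206, and 0.690 with estimated correlation, as were adipocyte genes (0 of 10 passed, or 0 and 0 over the list alone), camera adjusted p = 0.0370, and 0.799 with estimated correlation. Without CIC LOF 1 and p53 KO 2 the interferon, adipocyte and handling stress calls ended (0.316, 0.228 and 0.0870). The last 2 ended with a filter at 50 (0.0548 and 0.0581), adipocyte with quantile scaling (0.0787) or a pseudocount of 10 (0.0512) and handling stress with only these groups fitted (0.0759). The Spred3, Egr1, Nr4a1, Sell, Jak1 and Odc1 calls ended without HrasG12V 2 or 3 or CIC LOF 3, among others (adjusted p up to 0.293).

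Within CIC LOF, the 3 Etv4 LacZ carriers were set against the 2 tumours with wild-type Etv4. Etv4 was 2249 ± 431 against 2006 ± 132 (log2 fold change 0.15, adjusted p = 0.967). Its SE (1.68) holds the wider spread of other groups, so no change can be judged, nor the allele checked. Etv5 was 4285 ± 413 against 3629.8 ± 153, adjusted p = 0.885. Cic was higher in the carriers (6200.1 ± 451 against 2571 ± 553, log2 fold change 1.28, SE 0.24, adjusted p = 0.0190). Carriers had more Rag2, which recombines T cell receptor genes (1831 ± 755 against 16.9 ± 10.4, adjusted p = 0.0497). Bst1, Sertad4, Dixdc1, Hmgcs2 of ketone synthesis and Mef2b had log2 fold changes of 5.24, 5.13, 5.01, 4.82 and 4.77 (adjusted p at most 0.0413). They had less Strc (5.47 ± 9.47 against 1346 ± 824, adjusted p = 0.0176). Dapl1, Reg3g, the eosinophil genes Ear2 and Ccr3, and Gpr25 had log2 fold changes of -7.60, -6.35, -6.07, -5.54 and -5.52 (adjusted p at most 0.0483). In all 448 genes changed, 238 higher and 210 lower, and the share higher was 53.1%, and 42.5% of 367 with edgeR, 43.2% of 1825 with DESeq2 and under 50% without CIC LOF 1, 3, 4 or 5. Groups did not overlap at 6828 genes (43.6%; chance gives 20%). The count was 264, 115 and 79 without CIC LOF 3, 4 and 5, 195 with only these groups fitted and 209 with quantile scaling. None of the 19 named genes passed in every fit without 1 library, and Cic ended without CIC LOF 1, 2, 4 (adjusted p = 0.0505) or 5 (0.0642).

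Cdt1, which licenses DNA replication, was higher in carriers (6582 ± 558 against 2606 ± 489.9, log2 fold change 1.35, SE 0.24, adjusted p = 0.0169). E2f1 and Mcm5 had log2 fold changes of 1.26 and 1.20 (adjusted p at most 0.0371). Of the cell cycle genes, 3 of 30 rose, 0 fell and 27 did not pass (9 and 1 over the list alone), camera adjusted p = 1.43e-06, and 0.690 with estimated correlation. The receptor Notch3 was higher (17720.0 ± 4279 against 1474 ± 1600.4, adjusted p = 0.0409), as was Pfkl (6991 ± 589 against 3010.2 ± 1203, adjusted p = 0.0140). In the glycolysis and hypoxia list 2 of 20 rose, 0 fell and 18 did not pass, or 5 and 0 over the list alone, camera adjusted p = 0.00115, and 0.690 with estimated correlation. The macrophage gene Mpeg1 was lower (2894 ± 498 against 9718 ± 1294, adjusted p = 0.0303). Macrophage and granulocyte genes (0 of 17 rose, 1 fell and 16 did not pass, or 0 and 9 over the list alone) gave camera adjusted p = 5.93e-05, and 0.690 with estimated correlation. Thymic epithelium genes (0 of 17 passed, or 0 and 0 over the list alone), held mainly by CIC LOF 1, gave camera adjusted p = 0.00159, and 0.690 with estimated correlation. Mature T cell genes (0 of 18 passed, or 0 and 1 over the list alone) were lower, camera adjusted p = 0.0250, and 0.690 with estimated correlation. So were dendritic cell and MHC class II genes (0 of 14 passed, or 0 and 2 over the list alone), camera adjusted p = 0.00162, and 0.736 with estimated correlation. CIC LOF 1 made both differences (−1.12 and −0.06), since CIC LOF 2 (−2.86 and −2.94) lay within the carriers (−3.71 to −2.65 and −3.86 to −2.72). The same held for glycolysis (0.28 in CIC LOF 1, 1.11 in CIC LOF 2). MYC and ribosome biogenesis (1 of 24 rose, 0 fell and 23 did not pass, or 1 and 0 over the list alone) gave camera adjusted p = 6.43e-05, and 0.690 with estimated correlation. Without CIC LOF 1 and p53 KO 2 the mature T cell, MYC, glycolysis, epithelium and dendritic cell calls ended. The CIC targets list was not called (camera adjusted p = 0.890), with a median of 0.15 and a mean of −0.31. Each gene named here ended without CIC LOF 5 (adjusted p up to 0.317 over the libraries left out). A lone wild-type library left by omitting CIC LOF 1 or 2 was assumed to vary like the other groups.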

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

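All tests in this part were chosen after the result was seen. A library far from the rest of its group was sought in 344 sets of values, in which chance alone picks about 1 in 20, or 17.2; 25 were found, and 14 of the 16 in CIC LOF belonged to CIC LOF 1. In CIC LOF 1 these genes stood above the other 4 tumours: Ascl1 at 92.6 (0 elsewhere), Skint10 at 150.3 (0 to 1.13), Psmb11 at 977 (8.75 to 16.9), Ccl25 at 5039 (64.5 to 101), S100a8 at 99.01 (6.13 to 9.03), Tox2 at 371 (10.2 to 25.8), Nefm at 129 (0 to 2.26) and Snap91 at 220.1 (0 to 3.39). The NK and gamma delta T cell list score was also higher there, at −0.008 (−2.88 to −2.49). Below the other 4 lay Ldha at 24010 (42667 to 53229), Aldoa at 8054 (13349 to 15935), Cad at 2957 (8935 to 9755), Wdr25 at 93.3 (2875 to 7064) and Sestd1 at 794 (2006 to 2921). Also far from their groups were Stat2 at 1042 in CIC LOF 2 (1554 to 1814) and Alpl at 9.03 in CIC LOF 3 (16.4 to 19.9).

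Among p53 KO tumours Pole was low in p53 KO 2, at 2814 (4624 to 4943). In p53 KO 1 Dusp6 was high at 9059 (407 to 478), and Egfl7 at 598 (645 to 655) and Ercc5 at 414 (587 to 601) were low. In p53 KO 3 Ei24 at 1924 (1051 to 1101) and Polr1b at 3152 (1693 to 1729) were high. Dlx2 had 0 reads there against 1 elsewhere, within counting error, and the T-ALL list score was low at −0.93 (−0.06 to 0.10). The mature T cell score was low in p53 KO 4, at −2.15 (−1.04 to −0.87). No cause was tested for these, nor whether the 9 exceed chance.

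CIC LOF 1 and p53 KO 2 lay near thymus on the first component, but depth was excluded. After thinning to 1 depth CIC LOF 1 stayed at −60.8, against −23.5 for the nearest other tumour. Normal double positive thymocytes in CIC LOF 1 were excluded too: 4 of 16 abundant members were under 10% of thymus (Rag2 0.43%). Thymic epithelium in CIC LOF 1 had no independent test. Of 8 abundant members besides Psmb11 and Ccl25 the lowest, Prss16 (16.3% of thymus), had been seen before. Epithelial RNA stays a candidate source. A whole normal thymus was excluded in p53 KO 2, where 3 of 10 abundant members were under 10%. Its double positive genes do not part normal cells from that tumour stage (lowest Cd4, 15.8%, and none under 10% in p53 KO 4 either). Chromosome medians in p53 KO 2, −0.48 to 0.70 (log2, thymus −0.011 to 0.017), argue against mostly normal cells. A biological difference stays open and was not tested.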

How the results depend on the processing

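All settings but the pairs of libraries left out were planned. Few directions reversed, but filters, robust prior, fold minimum and 2-group fits cannot turn a gene's direction. Among single-gene values under settings other than a left-out library, 3020 kept direction and side of the threshold, 408 kept direction but no longer passed, 24 newly passed and 13 reversed. With 1 library left out these were 1055, 697, 5 and 12. Of results for called lists 660 kept direction and side, 108 no longer passed, 64 of them with an estimated correlation, and none reversed. Gene counts stayed within 1.5 times in 59 values and moved in 41, and in 12 and 38 with 1 library left out. The cause was not tested. The fit of all samples shares 1 variance per gene between groups of unequal spread, so p53 KO spread may be understated.

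Counts ranged with 1 library left out from 499 to 4836 (CIC LOF against thymus), 7 to 184 (HrasG12V against thymus), 3 to 2078 (p53 KO against thymus), 186 to 2113 (CIC LOF against p53 KO), 14 to 975 (HrasG12V against p53 KO), 10 to 200 (CIC LOF against HrasG12V) and 54 to 318 (Etv4 split). In that order, leaving out CIC LOF 1 and p53 KO 2 gave 5136, 2406, 2707, 1685, 399, 310 and 89. DESeq2 gave 2045, 2034, 2387, 1448, 594 and 1825 in all but the first. Array weights gave 9697, 6821 and 2117 against thymus, 22 for HrasG12V against p53 KO and 1306 for CIC LOF against HrasG12V. With edgeR CIC LOF and HrasG12V against thymus gave 2095 and 221, and HrasG12V against p53 KO gave 60. The 2 groups alone gave 6263 and 215 for HrasG12V and p53 KO against thymus, 28 and 6 for CIC LOF and HrasG12V against p53 KO, and 195 for the Etv4 split. Quantile scaling gave 1246 and 1702 for HrasG12V and p53 KO against thymus and 209 for the Etv4 split. HrasG12V against thymus gave 1392 with a pseudocount of 10, 1502 without a filter and 532 with a filter at 50. HrasG12V against p53 KO gave 52 without a filter, and p53 KO against thymus 600 with a 2-fold minimum. CIC LOF 1 and 2 alone gave 24, 10 and 50 against thymus, p53 KO and HrasG12V, and CIC LOF 3 to 5 alone 5393, 2590 and 374. Without p53 KO 1 and 3, CIC LOF against p53 KO gave 544.

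Each reversed value belonged to a gene that was not called. Cic in CIC LOF was −0.12 against thymus after quantile scaling, −0.65 and −0.33 against thymus and p53 KO with CIC LOF 1 and 2 alone, and 0.0563 and 0.26 against HrasG12V with array weights and with CIC LOF 3 to 5 alone. Kras was 0.0132 in CIC LOF against thymus with TMM, and without p53 KO 1 and 3 it was −0.61 in p53 KO against thymus and 0.56 in CIC LOF against p53 KO. In p53 KO against thymus Etv4 was −0.00645 with array weights and −1.15 without p53 KO 1 and 3, Spry4 was −0.24 without p53 KO 1 and 3, and Hras1 was −0.00508 without CIC LOF 1 and p53 KO 2. Etv5 in CIC LOF against HrasG12V was 0.0318 with array weights. Ranges with 1 library left out were −0.0330 to 0.37 (Cic) and −0.30 to 0.14 (Kras) for CIC LOF against thymus, and −0.40 to 2.70 (Etv4) for HrasG12V against thymus. For p53 KO against thymus they were −0.00508 to 0.12 (Hras1), −0.60 to 1.10 (Kras) and −1.04 to 1.16 (Etv4). Against p53 KO they were −1.14 to 0.56 (Kras, CIC LOF) and −0.66 to 2.45 (Etv4, HrasG12V), and −0.38 to 0.28 for Etv5 in CIC LOF against HrasG12V.

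The median log2 fold change of all genes moved by more than 0.1 with quantile scaling (0.18 and 0.12 for CIC LOF and p53 KO against thymus, 0.14 for the Etv4 split), with edgeR (0.12 for p53 KO against thymus, −0.11 for HrasG12V against p53 KO), with DESeq2 (0.14 for p53 KO against thymus), without a filter (−0.15 for CIC LOF and −0.15 for HrasG12V against thymus) and with a filter at 50 (0.11 for CIC LOF against thymus). No paired analysis was possible because the replicate numbers follow the order of deposit. Leaving out T cell receptor, immunoglobulin and mitochondrial genes was not run because the table holds no such genes. Depth limits what a count of 0 shows, as for Rxfp1 in p53 KO.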

Other observations

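The 6 counts of other splits of the samples were planned; all other tests in this part, and the genes named here, were chosen after the values were seen. NOTCH pathway genes varied within groups. Notch1, the receptor that drives early T cells, was 1972 in CIC LOF 1, 16391 in CIC LOF 2 and 50078, 52299 and 57978 in CIC LOF 3 to 5. In p53 KO 1 to 4 it was 706, 5082, 2789 and 36590.4. Its target Dtx1 was 48.4 in CIC LOF 1 against 3622, 16999, 30509.7 and 17333 in CIC LOF 2 to 5, and 11725 in p53 KO 4 against 1143, 127 and 97.5 in p53 KO 1 to 3. Ptcra, the pre-T cell receptor chain, was 25.6 in CIC LOF 1, 6209 in CIC LOF 4 and 5963 in p53 KO 4.

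p53 KO 1 and p53 KO 3 had little of the T cell factors Tcf7 (2126 and 458, against 52188, 58695 and 55852 in thymus) and Lef1 (789.8 and 105, against 4426, 5201 and 4603). The phosphatase gene Pten was 379 in CIC LOF 3, 266 in CIC LOF 5 and 661 in p53 KO 3, against 7413, 7349 and 7224 in thymus.

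Kras and other genes of chromosome 6 stood far above the other p53 KO libraries in p53 KO 1, with Kras at 44858 and the cyclin gene Ccnd2 (chromosome 6, 127125162 to 127152188) at 136152. Raised genes lying together in a region met their test: 19 of 491 genes were over 8-fold and formed 5 neighbouring pairs, a number that a share of 4e-04 of shuffles reached. Reads shared between Kras and the other Ras genes were excluded for Kras, since the higher of Hras1 and Nras stood at a log2 ratio of 0.929, against 4.58 for Kras. No DNA was measured, so a gain of DNA copies was not tested.

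Genes of chromosome 15, which carries Myc, lay above thymus in CIC LOF 1, HrasG12V 1 and p53 KO 1 to 4, with medians of 0.35 to 0.49 over 426 genes, against −0.03 to 0.04 in the other tumours. GC content was excluded (lowest median 0.34 without its trend). So were a few genes or 1 part of the chromosome (lowest of 3 parts 0.25). Random gene sets (share 1e-04, highest 0.20) cannot exclude chance, as these medians picked chromosome and libraries. Chromosome 15 did not stand alone in p53 KO: medians were 0.51 for chromosome 3 and −0.47 for chromosome 9 in p53 KO 1, 0.70 for chromosome 14 in p53 KO 2, 0.43 to 0.50 for chromosome 4 in p53 KO 2 to 4, −0.49 for chromosome 19 in p53 KO 3 and 0.55 for chromosome 5 in p53 KO 4. An extra chromosome 15 may explain its shift, as a hypothesis from the same data.

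Other splits of the samples into groups of equal sizes tested chance. For CIC LOF against thymus (3334 genes) 2 of 56 splits reached the count. The highest other, 3670, set CIC LOF 3 to 5 against CIC LOF 1 and 2 with thymus. For CIC LOF against HrasG12V (128) 2 of 56 splits did. There 220 came from CIC LOF 3 to 5 against CIC LOF 1 and 2 with HrasG12V. These shares lie under 0.05 unadjusted, but other splits gave more genes, so chance was not excluded. Chance was not excluded for p53 KO against thymus (934; 2 of 35 splits, highest other 1596, with p53 KO 2 beside thymus), CIC LOF against p53 KO (876; 5 of 100 drawn splits, highest other 2126, with p53 KO 4 beside CIC LOF 2 to 5) or HrasG12V against p53 KO (112; 2 of 35 splits, highest other 939, with p53 KO 4 beside HrasG12V). For HrasG12V against thymus (810; highest other 0) the 10 splits are too few for a share under 0.05.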
